A study of Rattus norvegicus with 11 samples.

How the data were processed

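The deposited table holds FPKM values, which the authors made from reads aligned to rn6; per the submitters' processing notes the tools were FastQC 0.11.9, cutadapt 1.18, STAR 2.7.1a, SAMtools 1.3.1, Cufflinks 0.17.3 and HTSeq 0.13.5. The notes as used here do not tie a tool to the FPKM step and give no strandedness. Per the labels, RNA was extracted with TRIzol, mRNA was captured on beads, libraries of 200 to 300 bp were made with a VAHTS kit, and sequencing was on an Illumina NovaSeq. The table has 32883 genes in 11 libraries, 388 without a gene name. For 192 names on more than 1 line the line with the highest mean was used. FPKM summed to 424200 to 442750 per library.

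FPKM values of a library fall on steps set by its depth and the gene length. Whole reads were recovered for 21487 of 21487 genes above 0 (relative tolerance 1e-08, at most 0.1 read). They are the smallest whole numbers with the ratios seen, so reads of sparse genes may be too low. A gene above 0 in only 1 library always gave 1 read, so its recovery was fixed in advance. Recovered reads served for depth, for the floor of zeros and for an alternative fit, not for the tests reported. Values were taken as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were kept. All 11 libraries entered a single limma fit (lmFit, then eBayes with a trend) without a block, and each of the 3 contrasts was adjusted by Benjamini-Hochberg, with calls at adjusted p under 0.05. The authors' scaling was kept.

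Before any value was seen, 40 gene lists were written. They cover osteoblast, adipocyte, chondrocyte and mesenchymal stromal markers, collagen and matrix, matrix proteases and inhibitors, contractile genes, TGF-beta, BMP, Wnt and p53 targets, interferon response, NF-kB and inflammatory genes, MHC class I and class II presentation and complement. They also cover cell cycle, senescence secretome, oxidative stress (NRF2), amino acid response (ATF4), unfolded protein response, heat shock, hypoxia and glycolysis, cholesterol synthesis, immediate early genes, osteoclast support factors, growth factors, lysosome, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes and histones. The rest are markers of dendritic cells and macrophages, neutrophils, endothelium, osteoclasts, skeletal muscle, Schwann cells, erythroid cells and lymphocytes. Lists with at least 3 measured members, 34 in all, were tested with camera at the preset correlation of 0.01, adjusted over the 34 lists. Camera with an estimated correlation and fry were run beside it. A member rose or fell where it passed the threshold of the genes. List medians are given relative to the median of all genes.

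Genes named in the text follow a rule fixed beforehand. It takes the 8 highest and 8 lowest fold changes of each comparison that pass, have a symbol, a mean of at least 5 FPKM in the higher group and no overlap between the groups. It adds up to 4 passing members of each list with the largest fold changes, and 15 genes in every comparison: Runx2, Sp7, Alpl, Bglap, Ibsp, Spp1, Col1a1, Pparg, Sox9, Tnfsf11, Tnfrsf11b, Cxcl12, Il6, Cdkn1a and Ptprc. Other genes named were chosen after their values were seen, which holds for a list member that went against its list. Fold changes of genes with 0 or 1 read in a library are given as levels.

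The alternatives planned were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, TMM-like scaling, quantile normalization, a fit of only the libraries compared, a replicate block, no trend, array weights, a minimum 2-fold change, and leaving out each library. Added after the data were seen were voom on recovered reads and removal of a lowess curve on gene length. In libraries simulated from the recovered reads with known changes, 100%, 91.8% and 83.3% of 1.5-fold changes and 98.0%, 95.9% and 93.5% of 2-fold changes were found in the comparisons of imDC with control, IRDC with control and IRDC with imDC. Of the smallest changes simulated, under 1.5-fold, 70.8%, 78.3% and 72.9% were found. Of unchanged genes, 0.091%, 0.0992% and 0.108% were called. Each size of change rested on 46 to 50 genes, every group had the control profile, and a single dispersion from genes with many reads was used. In the data most genes were called, so these percentages are not error rates of the calls reported here. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9.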

Results

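Bone marrow mesenchymal stem cells (BMSCs) are the adherent stromal cells of marrow, which can form bone, fat and cartilage cells in culture. Messenger RNA of rat BMSCs was sequenced at day 3 in 11 libraries of 3 groups, with 4 control libraries, 3 labelled imDC and 4 labelled IRDC. The series text describes BMSCs given medium conditioned by dendritic cells, which are antigen-presenting immune cells, either unirradiated (0 Gy) or irradiated (8 Gy), beside controls. The titles give no dose, so reading imDC as the unirradiated and IRDC as the irradiated arm rests on the names. Expression was given as FPKM (fragments per kilobase of transcript, scaled to library depth) for 32883 genes of the rn6 annotation, and 12521 genes with at least 1 FPKM in at least 3 libraries were tested. The values resolved into whole reads, which gave a depth of 17.8 to 25.5 M reads per library, with means of 22.7 M in control, 18.8 M in imDC and 21.2 M in IRDC. A single read on 1 kb of transcript was worth 0.0392 to 0.0562 FPKM. The titles call the libraries biological replicates, but no label states whether those of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. In the 4280 genes with the most reads, libraries of a group differed by a median coefficient of variation of 1.95% beyond counting error. Values below are mean FPKM ± SD (n = 4 for control, n = 3 for imDC and n = 4 for IRDC), and fold changes are on the log2(FPKM + 1) scale with their standard error (SE), which understates the change of low genes.

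Libraries of the 3 groups lay apart from each other. The first principal component held 81.2% of the variance and placed control libraries at a mean of -52.6, imDC at 4.87 and IRDC at 48.9. The second component, with 9.09% of the variance, set imDC at -23.7 against 7.70 in control and 10.0 in IRDC. Across genes, which are not independent replicates, Pearson's r was 0.992 to 0.994 between libraries of a group. It was 0.944 to 0.946 between control and imDC, 0.962 to 0.964 between imDC and IRDC, and 0.883 to 0.885 between control and IRDC.

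**Figure D1:**
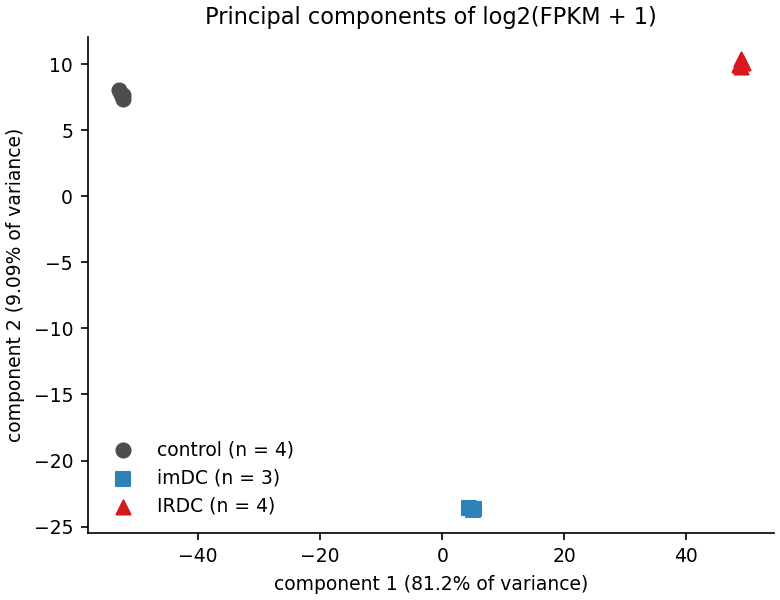
Principal components of log2(FPKM + 1) over 12521 genes, with component 1 (81.2% of the variance) on the x axis and component 2 (9.09%) on the y axis. Each point is a library of the control (n = 4), imDC (n = 3) or IRDC (n = 4) group, and imDC libraries lie between the other groups on component 1 and below them on component 2.

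The comparison of imDC with control set BMSC cultures given medium of unirradiated dendritic cells against controls. The labels used here give no number of medium batches per arm, and the medium of the controls is not described here. In both comparisons with control, products of dendritic cells therefore cannot be told apart from a batch or from other differences between the media. Of 29 dendritic cell and macrophage genes 20 passed the expression filter, with the macrophage gene Lyz2 at 519 ± 5.87 FPKM in control. Changes here and below therefore cannot be assigned to BMSCs alone. Inflammatory genes were among those with the largest increases. Lcn2, which encodes a siderophore-binding protein of innate immunity, rose from 1.77 ± 0.457 to 413 ± 2.72 FPKM, and Slpi, a secreted protease inhibitor, rose from 5.64 ± 1.83 to 653 ± 11.7 FPKM. Genes of the response to low oxygen rose as well, with Slc16a3, the lactate exporter, going from 7.01 ± 0.0992 to 148 ± 1.90 FPKM. Genes of cholesterol synthesis fell, with the isomerase gene Idi1 going from 57.6 ± 1.52 to 17.0 ± 1.34 FPKM. Alpl, which encodes the alkaline phosphatase of early osteoblasts, fell from 29.6 ± 0.678 to 4.50 ± 0.208 FPKM. Pparg, the main transcription factor of fat cell formation, fell from 17.1 ± 1.05 to 4.58 ± 0.813 FPKM.

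Of 29 measured members of the NF-kB and inflammatory list, 27 rose, 1 fell and 1 did not pass. The chemokine gene Ccl20 rose by 6.38 (SE 0.097), complement C3 by 5.25 (SE 0.095) and the neutrophil chemokine gene Cxcl3 by 4.79 (SE 0.056). Vcam1, an adhesion molecule gene, was the member that decreased, and fell by 0.92 (SE 0.052). The list's median was 2.16 above that of all genes (camera adjusted p = 3.0e-19). In the hypoxia and glycolysis list, 21 of 22 measured members rose and none fell, among them Egln3, a hydroxylase that marks hypoxia-inducible factor for degradation, from 0.167 ± 0.0482 to 24.0 ± 0.278 FPKM, Ca9, a carbonic anhydrase gene, by 3.09 (SE 0.074), and Bnip3, a mitophagy receptor gene, from 51.2 ± 0.959 to 275 ± 4.58 FPKM. Its median was 1.31 above that of all genes (adjusted p = 6.0e-20). Angptl4, a secreted inhibitor of lipoprotein lipase outside both lists, rose from 4.22 ± 0.290 to 216 ± 3.33 FPKM. All 22 measured members of the cholesterol synthesis list fell, with a median of -1.07 relative to all genes (adjusted p = 8.1e-12). Hsd17b7 fell by 2.09 (SE 0.098), the decarboxylase gene Mvd fell by 1.67 (SE 0.065), and Sqle, which encodes squalene epoxidase, fell by 1.49 (SE 0.035).

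Proliferation genes were higher in imDC. In the cell cycle list 32 of 35 measured members rose, 1 fell and 2 did not pass, with a median of 1.07 relative to all genes (adjusted p = 1.0e-14). Rrm2, a subunit of ribonucleotide reductase, rose from 13.5 ± 0.413 to 47.9 ± 1.60 FPKM, Top2a, a topoisomerase of dividing cells, from 5.51 ± 0.358 to 18.0 ± 0.873 FPKM, and Cdk1, the mitotic kinase, from 8.84 ± 0.493 to 27.4 ± 3.05 FPKM. In the amino acid response list, targets of ATF4, 14 of 18 rose and 3 fell (adjusted p = 2.5e-07), including Stc2, a secreted glycoprotein gene, by 2.64 (SE 0.047), Ddit4, a stress-induced inhibitor of mTOR signalling, by 2.10 (SE 0.023), and Trib3 by 1.40 (SE 0.060). The unfolded protein response list had 11 of 16 risen and 2 fallen (adjusted p = 0.00067), with the chaperone gene Hspa5 higher by 0.51 (SE 0.018). The complement list had 6 of 9 risen and 2 fallen (adjusted p = 0.00092), and Serping1, the C1 inhibitor gene, rose by 2.04 (SE 0.039). Of 19 measured p53 targets, 16 fell and 2 rose (adjusted p = 3.0e-04). Gadd45a, a growth arrest gene, fell from 152 ± 3.79 to 57.8 ± 2.89 FPKM and the receptor gene Eda2r fell by 1.63 (SE 0.086). Btg2, an antiproliferative gene, rose by 1.70 (SE 0.038). Cdkn1a, which encodes the cell cycle inhibitor p21, fell from 295 ± 4.83 to 165 ± 0.880 FPKM.

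Other lists passed camera at the preset correlation only. Of 75 ribosomal protein genes, which share reads with near-identical copies and are uncertain one by one, 67 rose and 2 fell (adjusted p = 7.0e-22). Their median was 0.48 above that of all genes, and the adjusted p = 0.074 with an estimated correlation. Of 14 TGF-beta targets 8 rose and 5 fell (adjusted p = 0.0055, adjusted p = 0.095 with an estimated correlation). Of 20 interferon response genes 16 fell and 1 rose (adjusted p = 0.018, adjusted p = 0.0995 with an estimated correlation), with the interferon regulatory factor gene Irf7 going from 8.88 ± 0.536 to 3.40 ± 0.303 FPKM. The senescence secretome list had 13 of 22 risen and 8 fallen (adjusted p = 0.00067, adjusted p = 0.075 with an estimated correlation). The members that moved most were the cytokine gene Il6, from 13.1 ± 0.632 to 236 ± 9.72 FPKM, the matrix protease gene Mmp3, from 9.62 ± 0.252 to 146 ± 1.88 FPKM, and Igfbp5, which encodes a binding protein of insulin-like growth factors, from 17.3 ± 0.340 to 0.791 ± 0.104 FPKM.

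Genes of bone and fat formation were mostly lower without their lists passing. Of 16 measured osteoblast genes 11 fell and 3 rose (adjusted p = 0.12). Besides Alpl, Smpd3, a sphingomyelinase gene, fell by 1.83 (SE 0.075) and Bmp4, which encodes a bone morphogenetic protein, fell to 25.6 ± 0.246 FPKM. Enpp1, whose product makes the mineralisation inhibitor pyrophosphate, rose by 1.82 (SE 0.027). Runx2, the osteoblast transcription factor gene, stood at 12.8 ± 0.671 in control and 11.9 ± 0.273 FPKM in imDC (adjusted p = 0.092), and Sp7 at 1.37 ± 0.381 and 1.83 ± 0.404 FPKM (adjusted p = 0.15). Spp1, the osteopontin gene, fell by 0.41 (SE 0.030), and Col1a1, the main collagen gene of bone matrix, rose by 0.43 (SE 0.016). Of 9 adipocyte genes 7 fell and 2 rose (adjusted p = 0.13). The cartilage transcription factor gene Sox9 fell by 0.45 (SE 0.12). Cxcl12, a chemokine gene of marrow stroma, rose from 506 ± 7.71 to 705 ± 3.01 FPKM. Tnfrsf11b, the osteoprotegerin gene, fell by 0.18 (SE 0.062, adjusted p = 0.025), a call lost without control replicate 1 or 3 or imDC replicate 2 or 3 (adjusted p = 0.060, 0.067, 0.064 and 0.11) and under both other scalings. Bglap and Ibsp lay under the expression filter, and Tnfsf11, which encodes the osteoclast factor RANKL, had 0 reads in each library, which allows up to 3 reads.

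In all, limma with Benjamini-Hochberg adjustment called 7912 of 12521 genes, 2895 higher and 5017 lower in imDC, and 860 of them changed at least 2-fold. The lowest fold changes among named genes were those of Cavin2, a caveola gene, from 60.4 ± 0.792 to 3.53 ± 0.585 FPKM, and Itm2a, a membrane protein gene, from 45.1 ± 2.38 to 3.34 ± 0.783 FPKM. No libraries of the groups overlapped in 62.8% of genes, where chance gives 5.71%. Camera passed 15 of 34 lists, and 8 of these kept their call with an estimated correlation. The counts of members were the same when adjusted over the list alone, except in the heat shock, oxidative phosphorylation and histone lists. The median of all genes was -0.089, so 36.6% of calls were higher; with TMM-like scaling, which shifts that median by 0.088, 50.3% were.

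The comparison of IRDC with control set medium of irradiated dendritic cells against controls, with the same limits on the medium. Several genes that led the comparison of imDC with control were higher still in IRDC. Lcn2 stood at 1194 ± 11.1 FPKM in IRDC, Slpi at 1946 ± 14.9 and Il6 at 667 ± 17.5. Other genes raised in imDC were lower in IRDC than in imDC. Ndufa4l2 was at 79.7 to 88.9 FPKM in imDC libraries and 61.9 to 67.3 in IRDC libraries. Wfdc18 had 1452 to 1685 reads in imDC libraries and 688 to 772 in IRDC libraries. Il1a, which encodes an inflammatory cytokine, went from 0.135 ± 0.104 in control to 146 ± 5.32 FPKM, Csf3, the granulocyte colony-stimulating factor gene, from 0.103 ± 0.0535 to 130 ± 3.31, and Ptges, a prostaglandin E synthase gene, from 1.62 ± 0.232 to 223 ± 1.45. Among genes that fell, Ca3, a carbonic anhydrase gene, went from 349 ± 5.19 to 0.150 ± 0.0908 FPKM, Ccn5, a matricellular protein gene, from 166 ± 3.00 to 1.03 ± 0.0909, and Scd, the stearoyl-CoA desaturase gene, from 77.0 ± 1.91 to 1.22 ± 0.127.

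Of the 29 NF-kB and inflammatory genes 27 rose and 1 fell (median 3.16 relative to all genes, adjusted p = 6.7e-18), with Ccl20 higher by 7.93 (SE 0.090) and Cxcl3 by 6.29 (SE 0.051). Of 22 hypoxia and glycolysis genes 21 rose and none fell (median 1.53, adjusted p = 6.1e-18), with Egln3 at 69.7 ± 1.81 FPKM, Slc16a3 at 270 ± 3.59 and the glucose transporter gene Slc2a1 going from 21.9 ± 0.462 to 194 ± 3.17. All 22 cholesterol synthesis genes fell (median -1.85, adjusted p = 1.6e-09). Hmgcs1, which makes the precursor of mevalonate, fell from 204 ± 3.71 to 21.8 ± 0.467 FPKM, Acat2 from 37.1 ± 1.99 to 3.55 ± 0.517 and Idi1 to 5.99 ± 0.518. Amino acid response genes rose in 14 of 18 cases and fell in 4 (median 1.09, adjusted p = 2.4e-06), with Vldlr, a lipoprotein receptor gene, higher by 2.72 (SE 0.025). Of 19 p53 targets 17 fell and 2 rose (median -0.84, adjusted p = 9.3e-04), including the death receptor gene Fas, which fell by 2.25 (SE 0.044), and Tp53inp1, which fell by 2.38 (SE 0.042). Cdkn1a stood at 112 ± 4.17 FPKM.

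Of 20 interferon response genes 19 fell and 1 rose (median -0.98, adjusted p = 4.3e-04), with Irf7 at 0.743 ± 0.238 FPKM, while Gbp2, a guanylate-binding protein gene, fell by 2.31 (SE 0.070) and Irf1 fell by 1.94 (SE 0.070). Of 14 TGF-beta targets 10 rose and 3 fell (median 0.97, adjusted p = 2.9e-05), with Skil, a repressor of SMAD signalling, higher by 2.17 (SE 0.065) and Pmepa1 by 2.08 (SE 0.028). The unfolded protein response list had 10 of 16 risen and 4 fallen (median 0.40, adjusted p = 0.0048), a call lost under quantile normalization (adjusted p = 0.15). These lists kept their calls with an estimated correlation. Cell cycle genes rose in 28 of 35 cases and fell in 6 (median 0.70, adjusted p = 2.4e-06), with adjusted p = 0.052 with an estimated correlation. Rrm2 rose to 38.3 ± 0.891 FPKM, while Tyms, the thymidylate synthase gene, fell by 1.08 (SE 0.093). Complement genes rose in 6 of 9 cases and fell in 3 (adjusted p = 0.018), with adjusted p = 0.075 with an estimated correlation, 0.052 with TMM-like scaling and 0.093 with quantile normalization. Of 75 ribosomal protein genes 48 rose and 10 fell (median 0.34 relative to all genes, adjusted p = 7.4e-08), 26 rose and 28 fell under quantile normalization (adjusted p = 0.97), and adjusted p = 0.26 with an estimated correlation. Senescence secretome genes rose in 12 of 22 cases and fell in 10 (adjusted p = 0.0067, adjusted p = 0.12 with an estimated correlation, 0.11 with TMM-like scaling and 0.093 with quantile normalization), with the cell cycle inhibitor gene Cdkn2b falling from 43.2 ± 0.944 to 1.45 ± 0.189 FPKM.

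Of 9 adipocyte genes 7 fell and 1 rose (median -1.41 relative to all genes, adjusted p = 0.047). That call was lost with the 5 FPKM filter (adjusted p = 0.11), with only the libraries of both groups (0.051) and without control replicate 3 (0.054), and had adjusted p = 0.11 with an estimated correlation. Fabp4, a fatty acid carrier gene, fell from 86.1 ± 4.91 to 2.99 ± 0.420 FPKM, Pparg to 0.587 ± 0.143 and Cebpa, a transcription factor gene of fat cells, from 23.5 ± 0.371 to 3.28 ± 0.107. Of 16 osteoblast genes 10 fell and 2 rose (adjusted p = 0.29), with Bmp4 at 1.73 ± 0.141 FPKM, Alpl at 1.76 ± 0.239 and Spp1 at 69.2 ± 2.30, while Enpp1 rose to 143 ± 1.05. Col1a1 rose by 0.49 (SE 0.015). Runx2, at 12.6 ± 0.403 FPKM, did not pass (log2 change -0.02, adjusted p = 0.65), but was higher by 0.18 with TMM-like scaling (adjusted p = 0.0021) and by 0.13 with quantile normalization (adjusted p = 0.016). Sp7 was at 1.42 ± 0.343 FPKM (adjusted p = 0.85). Cxcl12 fell by 0.10 (SE 0.014) to 473 ± 3.57 FPKM, and was higher by 0.12 with TMM-like scaling. Tnfrsf11b fell to 2.66 ± 0.185 FPKM and Sox9 to 0.701 ± 0.172.

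Limma called 9517 of 12521 genes, 3070 higher and 6447 lower in IRDC than in control, and 1975 of them changed at least 2-fold. Libraries of the groups did not overlap in 70.2% of genes, where chance gives 2.86%. Camera passed 19 of 34 lists and 9 of these kept their call with an estimated correlation. With TMM-like scaling 13 lists passed, and with quantile normalization 13. The counts of members were the same when adjusted over the list alone. Among genes with the lowest fold changes, Cavin2 had 0 reads in at least 1 IRDC library (0.0297 ± 0.0208 FPKM), and Mir675 lies within H19, whose reads cannot be told from its own. The median of all genes was -0.18, and TMM-like scaling moved it by 0.19 and quantile normalization by 0.15. Of the calls, 32.3% were higher, against 51.5% with TMM-like scaling and 46.3% with quantile normalization, and 214 genes called both ways had the opposite direction under TMM-like scaling.

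**Figure D2:**
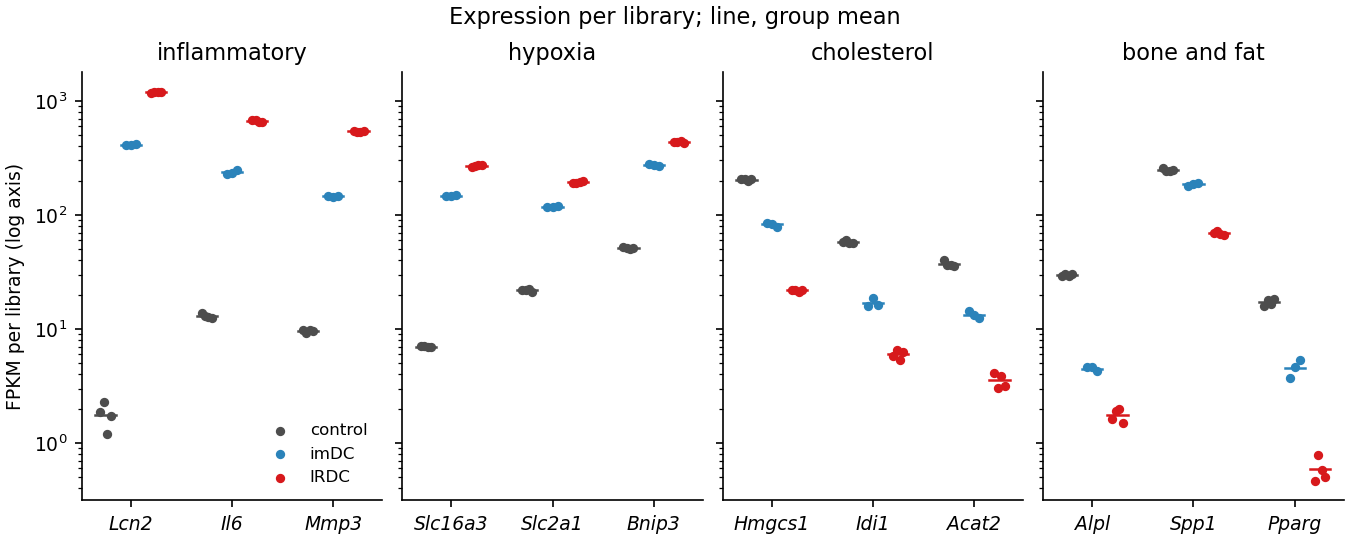
Expression of 12 genes in each library, in FPKM on a log axis, with points for single libraries of control (grey), imDC (blue) and IRDC (red) and a line at each group mean. Lcn2, Il6, Mmp3, Slc16a3, Slc2a1 and Bnip3 rise from control through imDC to IRDC, as Lcn2 from 1.77 to 413 and 1194 FPKM, and Hmgcs1, Idi1, Acat2, Alpl, Spp1 and Pparg fall, as Hmgcs1 from 204 to 82.5 and 21.8 FPKM. Only genes that keep 1 direction through the groups are shown. Among bone genes left out, Runx2 was at 12.8, 11.9 and 12.6 FPKM, and Col1a1 rose from 1764 to 2382 and 2470.

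The comparison of IRDC with imDC set medium of irradiated against medium of unirradiated dendritic cells. The labels used here give no number of medium batches per arm, so irradiation cannot be told apart from a difference between batches. Inflammatory genes were higher still in IRDC. Cxcl2, a neutrophil chemokine gene, rose from 9.65 ± 0.854 to 59.7 ± 2.42 FPKM, Il1a from 28.6 ± 2.42 to 146 ± 5.32, and Inhba, which encodes a subunit of activin, from 127 ± 4.23 to 568 ± 4.38. Ca3 fell from 64.9 ± 1.45 to 0.150 ± 0.0908 FPKM, Ccn5 from 46.2 ± 0.960 to 1.03 ± 0.0909, and Fabp4 from 52.5 ± 1.39 to 2.99 ± 0.420. Il1rl1, a cytokine receptor gene, fell from 124 ± 0.886 to 7.74 ± 0.482 FPKM and Npnt, a matrix protein gene, from 24.1 ± 2.73 to 0.508 ± 0.164.

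Of 29 NF-kB and inflammatory genes 23 rose and 4 fell (median 0.85 relative to all genes, adjusted p = 2.9e-11), with Mmp3 higher by 1.87 (SE 0.023), the cytokine gene Il1b by 1.64 (SE 0.11) and Il6 by 1.49 (SE 0.037). Vcam1 fell by 1.34 (SE 0.052). Of 22 hypoxia and glycolysis genes 18 rose and 1 fell (median 0.32, adjusted p = 4.3e-10), with Egln3 going from 24.0 ± 0.278 to 69.7 ± 1.81 FPKM, Slc16a3 higher by 0.87 (SE 0.021) and Vegfa, the vascular growth factor gene, by 0.68 (SE 0.016). Of 22 cholesterol synthesis genes 21 fell and 1 rose (median -0.84, adjusted p = 1.8e-09), with Hmgcs1 going from 82.5 ± 3.20 to 21.8 ± 0.467 FPKM and Dhcr7, the gene of the last step to cholesterol, from 7.97 ± 0.588 to 1.93 ± 0.424. Of 14 TGF-beta targets 11 rose and 2 fell (median 0.49, adjusted p = 2.4e-06), with Pmepa1 higher by 1.14 (SE 0.031). Of 20 interferon response genes 18 fell and 1 rose (median -0.73, adjusted p = 4.3e-05), with Gbp2 going from 9.75 ± 0.617 to 2.79 ± 0.297 FPKM. These 5 lists kept their calls with an estimated correlation.

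In the cell cycle list 31 of 35 members fell from imDC to IRDC and 1 rose (median -0.45 relative to all genes, adjusted p = 8.8e-06, adjusted p = 0.092 with an estimated correlation). Tyms fell by 0.90 (SE 0.10), Tk1, the thymidine kinase gene, fell by 0.88 (SE 0.060) and the mitotic activator gene Cdc20 fell by 0.89 (SE 0.12), while the cyclin gene Ccne2 was the member that rose, by 0.30. Of 75 ribosomal protein genes 66 fell and 1 rose (median -0.15, adjusted p = 4.3e-10, adjusted p = 0.21 with an estimated correlation). Of 70 nuclear genes of oxidative phosphorylation 60 fell and none rose (median -0.19, adjusted p = 3.6e-07), or 62 fell when adjusted over the list alone, with adjusted p = 0.21 with an estimated correlation. Ndufa4, a respiratory chain subunit gene, fell by 0.51 (SE 0.045). Of 13 mitochondrially encoded genes 11 fell and none rose (median -0.18, adjusted p = 8.9e-04, adjusted p = 0.29 with an estimated correlation), with Mt-atp6, a subunit of ATP synthase, falling from 2200 ± 29.1 to 1493 ± 48.2 FPKM. Of 19 p53 targets 13 fell and 2 rose (median -0.26, adjusted p = 0.020, adjusted p = 0.092 with an estimated correlation), or 14 fell when adjusted over the list alone. Of 18 amino acid response genes 10 rose and 7 fell (median 0.32, adjusted p = 0.011), with adjusted p = 0.15 with an estimated correlation and adjusted p = 0.061 with quantile normalization. Of 22 senescence secretome genes 12 rose and 7 fell (median 0.53, adjusted p = 0.0013, adjusted p = 0.097 with an estimated correlation), and Cdkn2a, the gene of a cell cycle inhibitor, fell by 2.17 (SE 0.092). Unfolded protein response (2 of 16 risen and 8 fallen, adjusted p = 0.44) and complement (4 risen and 4 fallen of 9, adjusted p = 0.87) did not pass, and under TMM-like scaling 6 of the former rose and 3 fell.

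Of 9 adipocyte genes 7 fell and 1 rose (median -0.40 relative to all genes, adjusted p = 0.020, adjusted p = 0.092 with an estimated correlation), and Pparg fell by 1.81 (SE 0.10) and Cebpa fell by 1.57 (SE 0.041). Osteoblast genes did not pass as a list, with 6 of 16 fallen and 4 risen (adjusted p = 0.84), while Bmp4 fell by 3.29 (SE 0.042), Spp1 fell by 1.42 (SE 0.030) and Alpl fell by 1.00 (SE 0.066). Col1a1 was higher by 0.05 (SE 0.016, adjusted p = 0.014), a call lost without the filter (adjusted p = 0.079), without the variance trend (0.12), with the length trend removed (0.51) and without imDC replicate 3 (0.058). Runx2 did not pass (log2 change 0.07, adjusted p = 0.20), but passed with TMM-like scaling (0.18, adjusted p = 0.0048) and quantile normalization (0.15, adjusted p = 0.017), and Sp7 did not pass (adjusted p = 0.21). Cxcl12 fell by 0.57 (SE 0.015), Tnfrsf11b fell by 1.40 (SE 0.062) and Cdkn1a fell by 0.55 (SE 0.026). Sox9 fell by 0.43 (SE 0.12), a call lost under quantile normalization (adjusted p = 0.20).

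Limma called 7362 of 12521 genes, 2535 higher and 4827 lower in IRDC than in imDC, and 644 of them changed at least 2-fold. Libraries of the groups did not overlap in 59.0% of genes, where chance gives 5.71%. Camera passed 15 of 34 lists and 5 of these kept their call with an estimated correlation. With TMM-like scaling 15 lists passed, and with quantile normalization 14. Each of these counts includes the dendritic cell and macrophage list, which did not pass without them, so not every list called here kept its call under either scaling. The median of all genes was -0.091, and TMM-like scaling and quantile normalization both moved it by 0.10. Higher genes made up 34.4% of the calls, 53.2% with TMM-like scaling and 50.2% with quantile normalization.

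**Figure D3:**
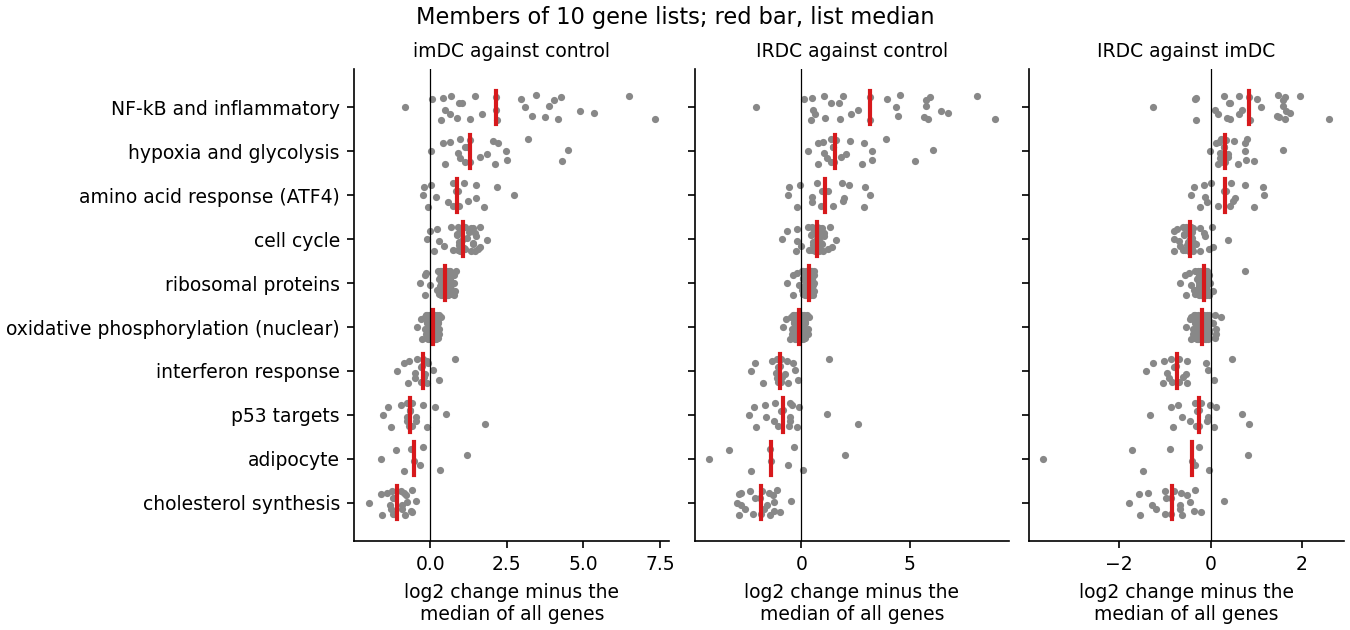
Members of 10 gene lists in the 3 comparisons, as log2 change minus the median of all genes on the x axis, with a grey point per gene and a red bar at the list median. NF-kB and inflammatory genes have medians of 2.16, 3.16 and 0.85, cholesterol synthesis genes of -1.07, -1.85 and -0.84, and cell cycle genes of 1.07, 0.70 and -0.45; the ribosomal protein list, with medians of 0.48, 0.34 and -0.15, has 26 genes risen and 28 fallen in IRDC against control under quantile normalization.

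The comparisons of imDC and of IRDC with control shared most of their calls. In both, 2168 genes were higher and 4420 lower, while 380 went opposite ways. Lists drawn independently would share 709.8 higher and 2583 lower genes. The covariance of the fold changes was 0.453, against 0.00500 in 100 simulations of groups without an effect against the same controls, and with the controls split between the comparisons (6 ways) it was 0.445 to 0.448, with 5852 to 5943 genes called in the same direction in place of 6588. Pearson's r across genes was 0.869, and 0.842 to 0.851 with the controls split; shared controls gave 0.464 in the simulation. By direction, 1208 genes rose in imDC and rose further in IRDC, 926 rose in imDC and fell from imDC to IRDC, 2499 fell in both steps, and 675 fell in imDC and rose from imDC to IRDC, each step past its threshold. Lcn2, Mmp3 and Egln3 were among those that rose in both steps, Hmgcs1, Bmp4 and Pparg among those that fell in both, and Tk1 and Cxcl12 among those that rose and then fell. The balance of directions depends on scaling. With TMM-like scaling 50.3% of calls were higher in imDC against control and 53.2% in IRDC against imDC. The comparisons with control then shared 6089 genes in direction. Both steps use the imDC libraries, whose errors push the steps opposite ways, and no simulation covered these classes.

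**Figure D4:**
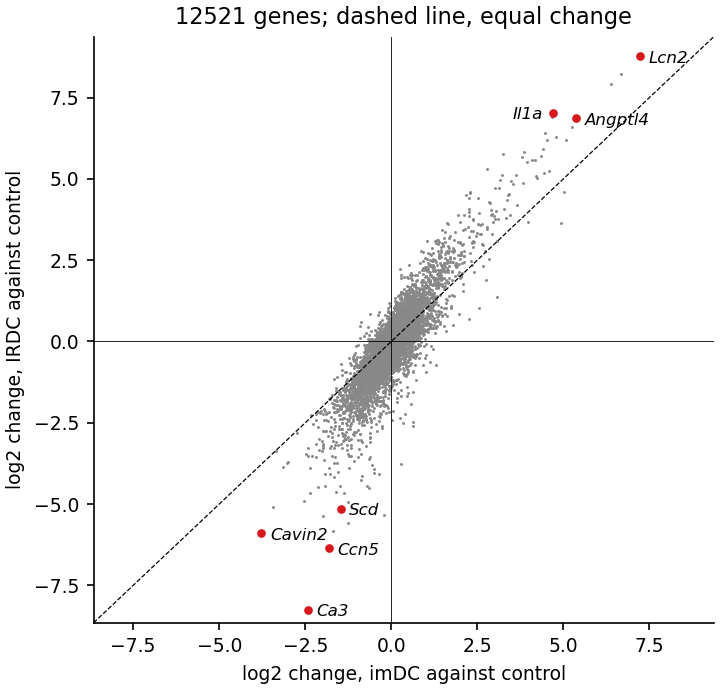
Log2 fold change of 12521 genes in imDC against control (x axis) and in IRDC against control (y axis), on the log2(FPKM + 1) scale, with a grey point per gene, 7 genes marked in red and a dashed line at equal change. Pearson's r is 0.869 across genes, and 0.842 to 0.851 with the controls split between the comparisons.

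Markers of other cell types were present and went different ways. Of 20 measured dendritic cell and macrophage genes, 9 rose and 10 fell in imDC (adjusted p = 0.32), 7 rose and 13 fell in IRDC against control (adjusted p = 0.83), and 3 rose and 12 fell in IRDC against imDC (adjusted p = 0.057), or 13 fell when adjusted over the list alone. The last list passed with TMM-like scaling (adjusted p = 0.026) and quantile normalization (adjusted p = 0.031). Lyz2, the lysozyme gene of macrophages, was abundant in all groups, at 519 ± 5.87 FPKM in control, 496 ± 11.2 in imDC and 185 ± 3.25 in IRDC. Ptprc, the pan-leukocyte gene, fell from 17.6 ± 0.723 to 8.48 ± 0.931 and 5.23 ± 0.142 FPKM, and Cd83, a gene of mature dendritic cells, from 5.72 ± 0.325 to 1.85 ± 0.297 and 0.576 ± 0.206. Cd163, a scavenger receptor gene of macrophages, rose from 0.957 ± 0.242 to 20.3 ± 0.306 and 27.5 ± 0.879 FPKM, and C1qc, a complement gene of macrophages, from 1.28 ± 0.507 to 10.3 ± 0.485 and 10.3 ± 0.267. Cd74, the only measured gene of the class II presentation list and a member of the dendritic cell list too, was at 2.63 ± 0.589, 6.29 ± 0.454 and 1.68 ± 0.198 FPKM. Of the osteoclast list, 4 genes were measured and it passed in no comparison (adjusted p = 0.16, 0.47 and 0.74), with Acp5, an acid phosphatase gene, rising from 7.24 ± 0.411 to 24.8 ± 0.417 and 43.7 ± 1.39 FPKM, and Ctsk falling from 214 ± 5.49 to 162 ± 0.455 and 130 ± 1.33. The Schwann cell list, with 4 measured genes, did not pass either (adjusted p = 0.31, 0.66 and 0.90). The neutrophil list had 2 measured genes (Camp and Mmp8), the endothelial and skeletal muscle lists 1 each (Tie1 and Tnnt3), and the erythroid and lymphocyte lists 0, so none was tested as a list.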

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

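The rule used here, Dixon's ratio of the gap of an extreme value to the range of its group, was set before the results were seen. It was applied to the genes named in the text and to the recovered reads, in groups of 4 libraries. It passed its critical value in 7 of 212 groups (3.30%), where chance gives about 1 in 20. In the control group the ratios were 0.909 for Acat2 (40.1 FPKM in replicate 1 against 35.9 to 36.2), 0.988 for Enpp1 (20.9 in replicate 2 against 19.5), 0.894 for Nt5e (21.1 in replicate 2 against 23.2 to 23.5), 0.923 for Ndufa4 (92.1 in replicate 3 against 104 to 105) and 0.831 for Camp (0 in replicate 4 against 0.105 to 0.127). In the IRDC group they were 1 for Ibsp (0.0493 in replicate 2 against 0) and 0.951 for Gbp2 (3.24 in replicate 2 against 2.63 to 2.66). Ibsp had 0 or 2 reads in IRDC libraries and Camp 0 or 2 in control libraries. Their ratios follow from the floor of zeros and cannot be set against that chance.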

How the results depend on the processing

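Voom and the removal of the length trend were chosen after the result was seen; all other settings were planned. Counts of calls were 6533 to 8445 (imDC against control), 7602 to 10773 (IRDC against control) and 6171 to 7570 (IRDC against imDC) over the other settings, and 7342 to 7621, 9244 to 9314 and 6739 to 7079 without single libraries. Voom gave 8087, 9702 and 7482 calls and removal of the length trend 7846, 9486 and 7280. With a 2-fold minimum, 860 genes (487 higher, 373 lower), 1975 (752 higher, 1223 lower) and 644 (211 higher, 433 lower) remained. TMM-like scaling called 4704 genes higher in IRDC than in control and 3823 higher in IRDC than in imDC. Lists past the threshold were 8, 9 and 5 with an estimated correlation and 33, 32 and 32 with fry. Direction turned for Mt-nd6 (-0.032) and Mt-nd2 (-0.018) in imDC against control with quantile normalization, for Runx2 in IRDC against control (0.18 with TMM-like scaling, 0.13 with quantile normalization) and for Cxcl12 there (0.12 with TMM-like scaling); both scalings set the bulk of genes near 0, and why the bulk lay below 0 was not tested. Fry and camera, which did not pass there, gave opposite directions for the chondrocyte list in IRDC against control (fry up, median -0.59) and for the mesenchymal (fry down, median 0.12) and Schwann (fry down, median -0.32) lists in IRDC against imDC, and the cause was not tested. All other named genes and lists kept their direction where called. A replicate block gave 7733, 9508 and 7110 calls. Of 10 same-number pairs none had a correlation over 0.1 (-0.0482 to 0.069), and 8 of 11 libraries correlated best with their own number, a hint from the data and not from the design. The hint rests mostly on control with IRDC, where same-number pairs had 0.0224 to 0.069. Same-number pairs with an imDC library had -0.0482 to 0.0409.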

Other observations

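The gene list tests and the splits were planned; the tests on depth, length, mixture, a single response and myeloid markers were chosen after the result was seen. The limits for the length trend and the mixture were written before their own values were computed.

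Matrix and growth factor genes changed in mixed directions. Fmod, which encodes a collagen-binding proteoglycan, rose from 2.17 ± 0.419 FPKM in control (n = 4) to 14.0 ± 0.292 in imDC (n = 3) and 52.6 ± 1.06 in IRDC (n = 4), and Plod2, a collagen crosslinking enzyme gene, to 335 ± 1.86 in imDC and 706 ± 14.8 in IRDC. Col6a1 fell from 397 ± 9.71 in control to 76.0 ± 2.12 FPKM in IRDC. Of 25 collagen and matrix genes 17 rose and 7 fell in imDC (adjusted p = 1.4e-04, adjusted p = 0.075 with an estimated correlation), 15 rose and 8 fell in IRDC against control (adjusted p = 4.3e-04, adjusted p = 0.082 with an estimated correlation), and 14 rose and 10 fell in IRDC against imDC (adjusted p = 0.027, adjusted p = 0.27 with an estimated correlation). Quantile normalization ended all 3 calls (adjusted p = 0.11, 0.15 and 0.55). Of 16 growth factor genes 10 rose and 6 fell in imDC (adjusted p = 0.049) and in IRDC against control (adjusted p = 0.016), with adjusted p = 0.095 and adjusted p = 0.064 with an estimated correlation, 0.11 and 0.16 with TMM-like scaling and 0.11 and 0.18 with quantile normalization, and 8 rose and 5 fell in IRDC against imDC (adjusted p = 0.057). Igf1, an insulin-like growth factor gene, fell from 39.3 ± 2.64 in control to 2.46 ± 0.339 FPKM in IRDC. Of 14 mesenchymal stromal markers 7 rose and 7 fell in imDC (adjusted p = 0.24), 9 rose and 5 fell in IRDC against control (adjusted p = 0.031, adjusted p = 0.082 with an estimated correlation, 0.10 with TMM-like scaling and 0.655 with quantile normalization), and 8 rose and 6 fell in IRDC against imDC (adjusted p = 0.29). Nt5e, a stromal surface enzyme gene, rose from 22.8 ± 1.11 to 82.9 ± 0.789 and 164 ± 4.24 FPKM.

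Of 12 Wnt targets and inhibitors 8 fell and 3 rose in imDC (adjusted p = 0.21), 11 fell and 1 rose in IRDC against control (adjusted p = 0.0051), and 9 fell and 2 rose in IRDC against imDC (adjusted p = 0.021, adjusted p = 0.092 with an estimated correlation). Lgr5, a Wnt pathway receptor gene, fell from 26.0 ± 1.14 in control to 2.99 ± 0.238 FPKM in IRDC. Of 17 lysosome genes 16 fell and 1 rose in imDC (adjusted p = 3.9e-06, adjusted p = 0.095 with an estimated correlation), 14 fell and 2 rose in IRDC against control (adjusted p = 0.0068, adjusted p = 0.31 with an estimated correlation and 0.057 with TMM-like scaling), and 9 fell and 7 rose in IRDC against imDC (adjusted p = 0.74), or 7 rose and 3 fell there with TMM-like scaling. Lamp1, a lysosomal membrane gene, fell from 405 ± 5.42 to 242 ± 0.372 FPKM in imDC. Of 70 oxidative phosphorylation genes 23 fell and 9 rose in imDC (adjusted p = 0.75), or 26 rose and 5 fell with TMM-like scaling, and 61 fell and 3 rose in IRDC against control (adjusted p = 6.8e-04, adjusted p = 0.39 with an estimated correlation and 0.095 with TMM-like scaling). Of 13 mitochondrially encoded genes 6 rose and 1 fell in imDC (adjusted p = 0.095), or 1 rose and 6 fell with quantile normalization, and 10 fell in IRDC against control (adjusted p = 0.10), or 6 rose and 3 fell with TMM-like scaling. The BMP, chondrocyte, protease, contractile, MHC class I, NRF2, heat shock, immediate early, osteoclast support and histone lists passed in no comparison (adjusted p = 0.073 to 0.80, 0.22 to 0.93 and 0.15 to 0.97). Among their members Prg4, the lubricin gene, rose from 5.23 ± 0.151 to 51.8 ± 0.320 and 52.5 ± 1.23 FPKM, and Cryab, a small heat shock protein gene, fell from 19.8 ± 0.514 to 3.63 ± 0.857 and 0.777 ± 0.183.

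The number of calls could come from any grouping of the libraries. In each comparison 1 of 35 splits called as many genes, the real grouping itself. The highest count of another split was 4090 in imDC against control, 0 in IRDC against control and 3221 in IRDC against imDC. Other splits mix groups that lie far apart, which adds the group difference to the spread. The real grouping was therefore bound to call most, and these counts do not measure chance. The splits do not show whether libraries of a group are separate cultures.

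The graded change of inflammatory, hypoxia and cholesterol genes could come from depth, gene length or mixing. Depth was lowest in imDC (18.8 M reads), which is not between the other groups. With the length trend removed, the list medians of IRDC against control kept at least 0.985 of their size. Fold changes followed gene length least in that comparison (Spearman's r = -0.0522). The ratio was not computed for imDC against control (r = -0.137) or IRDC against imDC (r = 0.0733), so it does not cover the steps of the graded change. For imDC as a mixture of control and IRDC RNA, 19.3% of the genes called in imDC against control (1530 of 7912) lay outside the range of the other groups in all 3 imDC libraries, 876 above and 654 below. For 1 response at 2 strengths, 87.3% of called members of the lists (62 of 71) moved further the same way in IRDC, against 3707 of 7912 genes called in imDC (46.9%), and the median log2 change of the cell cycle list from imDC to IRDC was -0.54. The lists were picked for these changes, so the values restate them and leave that question open.

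Myeloid markers went apart, which could come from a change in the share of myeloid cells or from dendritic cell RNA carried over. Over 1 on the log2 scale in IRDC against control, 4 of 20 markers rose and 4 fell. The question was put after the markers were seen to go apart, so these counts restate that pattern. A uniform change in the share of a single myeloid population would not give both directions. A shift between kinds of myeloid cells could, and was not tested. Of 10 dendritic cell genes, picked after the values were seen and in part shared with other myeloid cells, 6 were measured, with a median log2 change of -0.94 in IRDC and -0.44 in imDC. Cd74 rose in imDC, by 1.02 (SE 0.11), and RT1-Da, under the filter, was at 0.256 ± 0.0658 FPKM in control and 0.855 ± 0.114 in imDC. These values leave carried-over RNA open.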
